A study of Mus musculus with 39 samples.

How the data were processed

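Poly(A) RNA of RiboTag input lysates was sequenced from the BLA and the hippocampus of female mice aged 9 months, 39 libraries in all, each from a single mouse and tissue. Per the submitters' protocol notes, BLA libraries were made from 10 ng and hippocampal libraries from 50 ng of RNA, with paired-end reads of 2 × 50 bp. The gene counts were deposited by the authors as whole numbers per gene symbol and library without normalization, after trimming with Trimmomatic 0.39 and with genome build mm39, per the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. Each table holds 50559 genes, of which 48908 match a symbol of a mouse reference gene table of build GRCm38.p6. That table was used only for alternative names and for the order of neighbouring genes.

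Total counts run from 50.3 to 74.3 M in the BLA (median 59.3 M) and from 92.1 to 128 M in the hippocampus (median 109.9 M). The protocol notes give 40 M reads per sample. Among counts of 1 to 20, even numbers make up 58.5 to 69.0% in the BLA and 54.3 to 62.7% in the hippocampus. Counting the mates of a pair separately would give such an excess, but how mates were counted is not given. If they were counted separately, small counts rest on fewer fragments than their size. Mitochondrially encoded genes hold 1.77 to 4.06% of the BLA counts and 2.97 to 3.91% of the hippocampal counts. No library pair was a duplicate: the smallest chi-square per gene was 11.0 over 171 BLA pairs and 22.1 over 190 hippocampal pairs.

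Libraries were grouped by tissue, genotype and training as the labels give them. The comparisons, the test, the threshold, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, apart from the alternatives named below as chosen afterwards. In each tissue 6 comparisons were made: the genotype effect averaged over naive and trained mice with equal weights, the genotype effect in naive and in trained mice, the training effect in controls and in APP/Tau mice, and the interaction. A 13th comparison, over both tissues, tests whether the averaged genotype effect differs between the BLA and the hippocampus; it treats the libraries as independent although a mouse can have given both tissues.

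All libraries of a tissue entered a single fit with the 4 group means, in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 23168 genes in the BLA, 25791 in the hippocampus and 26725 in the fit over both tissues. TMM factors, trended dispersions and the quasi-likelihood F test (2-sided) were used, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of adjusted p < 0.05. Standard errors are the absolute log2 fold change over the square root of F, and 95% intervals are 1.96 standard errors. Levels are CPM with TMM factors. Where controls hold 0 counts, the ratio is given as a bound with a floor of 3 counts.

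The 38 gene lists cover transgene-related genes, microglial, astrocytic, oligodendrocytic, vascular, meningeal and choroid cells, blood, immediate early and delayed activity genes, synapses, receptors, channels, neuropeptides, interneurons, metabolism, stress, Alzheimer risk orthologs, regional neuron markers, neurogenesis, DNA damage, and sex and identity. All but the sex and identity list, of which 1 gene passed the filter, were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and again with the correlation estimated per list, with adjustment over the lists of a comparison. List members were also counted after adjustment over the list alone. A list score, the mean log2 CPM (prior count 2) of the list in a library, was tested by exact permutation of mice between the groups, within training groups where the effect is averaged; this test was chosen after seeing the data.

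Genes were named by rule: App, Mapt, Prnp, Gfap, Cst7, Trem2, Apoe and C4b in genotype comparisons and Fos, Arc, Npas4, Egr1 and Bdnf in training comparisons. To these come up to 6 rising and 6 falling genes with the largest change past the threshold and a mean of at least 1 CPM, leaving out unnamed predicted genes. For the 6 lists with most called members, up to 3 called members with the smallest p were added, and up to 2 for any other list described. Where fewer than 5 genes passed, the 5 genes with the smallest p are given. Genes named outside this rule are Prn, Xist, Lamr1-ps1 in the BLA, 4930590L14Rik, the Ugt1a genes, Gm41107, Tiam1 and Rpsa. Bach1, Grik1 and 2810407A14Rik are named as members of the chromosome 16 block. All of these were chosen after their values were seen. A few genes that the rule selects are not reported here.

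The alternatives were DESeq2 1.42.0 (Wald test), limma-voom, RLE factors, no filter on low counts, a filter at a mean of 1 CPM, a replicate block, only the 2 groups compared, only library numbers with both tissues, and each library left out in turn. Within a tissue the replicate block is the sample number of the title, which names different mice in each group. A call that this block ends can therefore be lost power alone. In the fit over both tissues the block is the library number. Lists were tested with fry as well. Chosen after seeing the data were leaving out the libraries with more than 0.5% of counts on 18S rRNA, and a covariate of central amygdala and striatum markers in the BLA. For each comparison 100 splits of the same libraries, the real grouping included, were fitted to see how many genes other groupings call. Runs of called genes that sit side by side were compared with 10000 shuffled gene orders.

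The fits were tested on simulated data: counts drawn with the mean levels, library sizes and dispersions of the real tables, in which sets of 200 genes each were changed by genotype, by training or by their interaction at folds of 1.5, 2 and 4. For the averaged genotype effect edgeR recovered 71.6%, 98.5% and 100% of the genes changed at these folds in the BLA and 83.6%, 97.0% and 100% in the hippocampus, with 7.69% and 11.8% of calls false. DESeq2 gave 20.6% and 21.7% false calls on the same data. These shares of the averaged effect leave out the genes changed by the interaction, which also change in it by a smaller fold. Those genes help set the adjusted threshold but are missing from the calls counted. Each share can therefore be overstated and cannot be set against the 5% aimed at. In naive mice, where these genes do not change, edgeR gave 4.76% false calls in the BLA and 4.52% in the hippocampus. For the training effects edgeR recovered 83.6% of genes changed 2-fold in BLA controls, 82.1% in BLA APP/Tau mice, 88.1% in hippocampal controls and 88.1% in hippocampal APP/Tau mice. For the interaction it recovered 58.2% in the BLA and 79.1% in the hippocampus. The changed genes had a mean of at least 1 CPM, and genes were drawn independently of each other. With sets of 200 changed genes the adjusted threshold is also easier to reach than where few genes change. Recovery in the real data can therefore be lower, above all for genes that vary widely between mice. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Reads, splicing and strand were not analysed here.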

Results

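Bulk RNA was sequenced from the basolateral amygdala (BLA) and the hippocampus of 9-month-old female mice, to ask how amyloid and tau pathology present together act on circuits of emotion and memory. APP/Tau mice carry human APP with the Swedish and Indiana mutations (line J9) and human tau with the P301S mutation (line PS19). Controls carry neither. All mice also carry a CaMKIIα-Cre driver and RiboTag, a tagged ribosomal protein. The libraries are the RiboTag "input", which is total tissue RNA taken before tagged ribosomes are pulled down, so every cell type of the tissue contributes. Trained mice went through cued fear conditioning, in which a tone ends with a foot shock, and were killed 1 h later. BLA tissue came from small punches of thick sections, so neighbouring nuclei can be present in a punch.

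The BLA groups hold 5 naive and 4 trained APP/Tau mice and 5 naive and 5 trained controls. The hippocampal groups hold 5 naive and 4 trained APP/Tau mice and 5 naive and 6 trained controls. Total counts per library run from 50.3 to 74.3 M in the BLA and from 92.1 to 128 M in the hippocampus, so small changes are easier to detect in the hippocampus. Levels are given as CPM after TMM scaling, mean ± SD over n mice, and changes as log2 fold change ± standard error. Each p-value is 2-sided.

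In the hippocampus of APP/Tau mice, transcripts assigned to App (the amyloid precursor protein) rose by 0.45 ± 0.04, those of Mapt (tau) by 0.22 ± 0.03 and those of Prnp (the prion protein) by 1.11 ± 0.05 (edgeR adjusted p = 6.6e-06, 0.000607 and 2.9e-11). App stood at 2483 ± 163 CPM in 9 APP/Tau mice and at 1819 ± 99.2 CPM in 11 controls, and Prnp at 1906 ± 193 against 872 ± 64.4 CPM. In the BLA only Prnp rose, by 0.58 ± 0.08 (adjusted p = 0.00234, edgeR), while App gave -0.15 ± 0.07 (adjusted p = 0.256) and Mapt 0.02 ± 0.06 (adjusted p = 0.897). Prn, which overlaps Prnp so that the same reads can count for either, rose by 1.41 ± 0.06 in the hippocampus and 0.78 ± 0.09 in the BLA; it was named after its values were seen. Mouse and human transcripts were not separated here, so these values add the endogenous gene to whatever transgene reads align to it. The list of transgene-related genes (App, Mapt, Prnp, Camk2a, Rpl22) has 3 of 5 genes up in the hippocampus, and 4 up and 1 down adjusted over the list alone. Its camera test gives adjusted p = 5.2e-06, and adjusted p = 0.0109 with an estimated correlation.

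The hippocampus of APP/Tau mice shows a broad rise of microglial and astrocytic genes. Gfap, the intermediate filament of reactive astrocytes, rose from 407 ± 49.9 CPM in 11 controls to 2266 ± 1646 CPM in 9 APP/Tau mice, a change of 2.48 ± 0.31. Genes of plaque-associated microglia rose too. Cst7, a cathepsin inhibitor, rose by 5.46 ± 0.70, Clec7a, a pattern receptor, by 6.10 ± 0.67, Itgax, an integrin, by 5.64 ± 0.62, and the lipid sensor Trem2 by 1.85 ± 0.27. The complement gene C4b rose by 2.60 ± 0.34 and the lipid carrier Apoe by 0.75 ± 0.19. The chemokine Cxcl13 rose by 4.70 ± 0.83 and the protease Ctse by 5.62 ± 1.03. Over naive and trained mice together 2854 of 25791 genes passed adjusted p < 0.05 (edgeR quasi-likelihood F test), 1875 up and 979 down. Leaving out each library in turn keeps 1045 of them in every fit. Of the hippocampal genes named for this effect, Apoe, Trf, Cacna2d1, Trpc6, Gpr161, Pclo, Idi1, ND4, Homer1, Enpp6, Crhr1, Rn7sk and Cdr1 lose their calls in at least 1 of these fits. limma-voom ends the calls of Cst7, Clec7a, Ctse and Cxcl13, whose levels vary widely between mice.

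**Figure D1:**
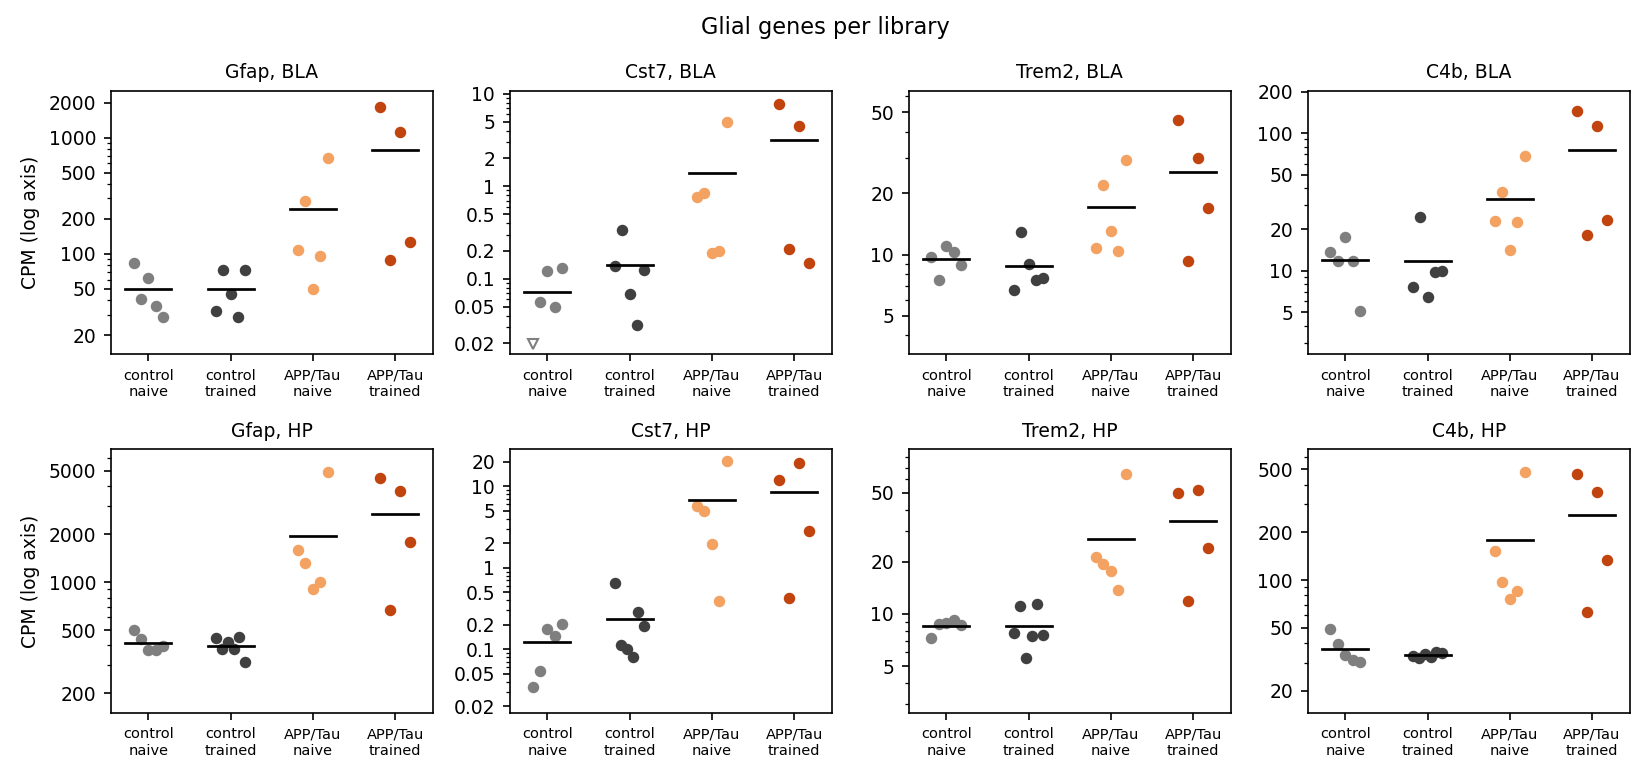
Levels of Gfap, Cst7, Trem2 and C4b in each library (CPM, log axis) for naive and trained control and APP/Tau mice in the BLA and the hippocampus; each point is a library, each line a group mean, and the open triangle a library with 0 counts. Hippocampal Gfap averages 407 CPM in controls and 2266 CPM in APP/Tau mice, with a wide spread among the APP/Tau mice.

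The disease-associated microglia list has 28 of 30 genes up in the hippocampus, and 29 adjusted over the list alone, with a median change of 1.63 (camera adjusted p = 7.2e-19, and adjusted p = 0.258 with an estimated correlation). Permuting mice exactly within training groups gives adjusted p = 0.00018 for its score. The chemokines Ccl3 and Ccl6 rose by 5.39 ± 0.47 and 3.73 ± 0.40. All 21 complement and antigen presentation genes rose, and 21 adjusted over the list alone (camera adjusted p = 2.3e-15, and adjusted p = 0.258 with an estimated correlation). C1qb and C1qc, subunits of the first complement component, rose by 1.76 ± 0.26 and 1.67 ± 0.25. Of 26 reactive astrocyte genes 22 rose, and 23 adjusted over the list alone (camera adjusted p = 1.9e-13, and adjusted p = 0.258 with an estimated correlation). The asparaginase Aspg rose by 2.20 ± 0.27 and the cytokine receptor Osmr by 2.09 ± 0.30. Interferon response genes rose in 18 of 22 cases, and in 21 adjusted over the list alone (camera adjusted p = 1.9e-13, and adjusted p = 0.258 with an estimated correlation). Ifit3, an interferon-induced antiviral gene, rose by 1.11 ± 0.15, its relative Ifit1 by 1.12 ± 0.19 and the chemokine Cxcl10 by 2.98 ± 0.43.

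Part of the genes of resting microglia, lysosomes, myelin and general astrocytes rose in the hippocampus too. Of 18 homeostatic microglia genes 12 rose, 15 adjusted over the list alone (camera adjusted p = 2.5e-10, and adjusted p = 0.258 with an estimated correlation). The protease Ctss rose by 1.71 ± 0.25 and the mannosidase Man2b1 by 0.98 ± 0.14. Their list of 26 lysosome and autophagy genes has 12 up and 1 down, and 14 and 1 adjusted over the list alone (camera adjusted p = 4.0e-06, and adjusted p = 0.270 with an estimated correlation). Gsn, an actin-severing protein, rose by 0.97 ± 0.21 and Trf, transferrin, by 0.71 ± 0.18. Myelin genes rose in 9 of 20 cases and in 18 adjusted over the list alone (camera adjusted p = 3.8e-09, and adjusted p = 0.280 with an estimated correlation). The water channel Aqp4 rose by 0.81 ± 0.18. General astrocyte genes rose in 9 of 15 cases, 10 adjusted over the list alone (camera adjusted p = 3.7e-05, and adjusted p = 0.280 with an estimated correlation).

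Among orthologs of Alzheimer risk genes, Spi1, a microglial transcription factor, rose by 1.27 ± 0.20 and Inpp5d, a lipid phosphatase, by 0.91 ± 0.15. That list has 8 of 26 genes up and 2 down, and 12 up and 4 down adjusted over the list alone (camera adjusted p = 0.00496, and adjusted p = 0.270 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, rose by 1.23 ± 0.27 and the death receptor Fas by 1.20 ± 0.28. DNA damage and p53 genes rose in 5 of 15 cases, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.0311, and adjusted p = 0.280 with an estimated correlation). The metallothioneins Mt2 and Mt1 rose by 1.02 ± 0.16 and 0.75 ± 0.14. Glucocorticoid response genes rose in 6 of 20 cases, 7 adjusted over the list alone (camera adjusted p = 0.00687, and adjusted p = 0.280 with an estimated correlation).

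Part of the genes of neurons and synapses fell in the hippocampus. The adhesion protein Nlgn3 fell by 0.25 ± 0.06 and the scaffold Shank1 by 0.30 ± 0.07. Of 34 glutamate receptor and postsynaptic genes 13 fell, and 28 did adjusted over the list alone, with a median of -0.23 (camera adjusted p = 1.1e-13, and adjusted p = 0.258 with an estimated correlation). These 13 include Grik1 (-0.88 ± 0.09), a member of the chromosome 16 block described below. Cacna2d1, a calcium channel subunit, fell by 0.31 ± 0.09. Voltage-gated channel genes fell in 6 of 25 cases, 12 adjusted over the list alone (camera adjusted p = 5.3e-07, and adjusted p = 0.270 with an estimated correlation). Among markers of dentate gyrus granule cells the transcription factor Prox1 fell by 0.48 ± 0.12 and the channel Trpc6 by 0.73 ± 0.19. Their list has 5 of 14 genes down, 7 adjusted over the list alone (camera adjusted p = 2.4e-06, and adjusted p = 0.270 with an estimated correlation). The ciliary receptor Gpr161, a marker of CA1 pyramidal cells, fell by 0.40 ± 0.11, with 4 of 10 CA1 genes down, 7 adjusted over the list alone (camera adjusted p = 0.000233, and adjusted p = 0.270 with an estimated correlation). CA3 markers gave 1 up of 10, the oxygenase Fmo1 at 0.53 ± 0.12, and 1 adjusted over the list alone (camera adjusted p = 0.716, and adjusted p = 0.913 with an estimated correlation).

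In other neuronal and metabolic groups few hippocampal genes were called. The active zone scaffold Pclo fell by 0.28 ± 0.08, a call that ends when the libraries rich in 18S rRNA are left out. Of 30 presynaptic genes 2 fell, with 0 adjusted over the list alone (camera adjusted p = 4.7e-06, and adjusted p = 0.280 with an estimated correlation). The GABA receptor subunit Gabrd fell by 0.22 ± 0.06, 1 of 15 such genes, with 3 adjusted over the list alone (camera adjusted p = 0.000175, and adjusted p = 0.270 with an estimated correlation). The sterol demethylase Cyp51 fell by 0.27 ± 0.07 and the isomerase Idi1 by 0.26 ± 0.08. They are 2 of 22 cholesterol synthesis genes, and 2 fell adjusted over the list alone (camera adjusted p = 1.5e-06, and adjusted p = 0.280 with an estimated correlation). ND4, a mitochondrially encoded subunit of complex I, fell by 0.19 ± 0.05. All 13 mitochondrially encoded genes lie below 0, with 2 called and 3 adjusted over the list alone (camera adjusted p = 1.8e-05, and adjusted p = 0.276 with an estimated correlation). Homer1, a synaptic scaffold, fell by 0.20 ± 0.06, a call that a replicate block ends. It is the 1 of 26 delayed activity genes that fell, with 0 adjusted over the list alone (camera adjusted p = 0.00579, and adjusted p = 0.280 with an estimated correlation).

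Some vascular, precursor and stress genes changed as well. The myosin chain Myl9 of vessel wall cells rose by 0.39 ± 0.09, with 7 of 20 endothelial and pericyte genes up, 11 adjusted over the list alone (camera adjusted p = 1.5e-06, and adjusted p = 0.270 with an estimated correlation). Enpp6, an enzyme of newly formed oligodendrocytes, rose by 0.61 ± 0.15, with 2 of 10 precursor genes up, 3 adjusted over the list alone (camera adjusted p = 0.00511, and adjusted p = 0.280 with an estimated correlation). Rarres2, the chemoattractant chemerin, rose by 0.51 ± 0.10. Its list of choroid plexus and ependyma genes has 2 of 17 up, 2 adjusted over the list alone (camera adjusted p = 0.000317, and adjusted p = 0.358 with an estimated correlation). Aebp1, a matrix protein, rose by 1.16 ± 0.25, the 1 of 13 meningeal fibroblast genes up, 1 adjusted over the list alone (camera adjusted p = 0.0676, and adjusted p = 0.510 with an estimated correlation). Ccn1, a matrix protein induced by activity and stretch, rose by 1.18 ± 0.25 while the nuclear receptor Nr4a2 fell by 0.42 ± 0.09. The 29 immediate early genes give 3 up and 2 down, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.810, and adjusted p = 0.951 with an estimated correlation). Atf3, a stress transcription factor, rose by 1.64 ± 0.32 and the kinase relative Trib3 by 0.82 ± 0.21. Of 25 heat shock and unfolded protein genes 2 rose and 1 fell, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.509, and adjusted p = 0.858 with an estimated correlation).

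Few genes of the remaining lists were called in the hippocampus. Hes5, a Notch target, fell by 0.63 ± 0.15, and neurogenesis genes gave 1 up and 2 down of 12, 2 and 2 adjusted over the list alone (camera adjusted p = 0.991, and adjusted p = 0.990 with an estimated correlation). Crhr1, the stress hormone receptor, fell by 0.38 ± 0.10. Neuropeptide genes fell in 2 of 27 cases, 2 adjusted over the list alone (camera adjusted p = 0.120, and adjusted p = 0.280 with an estimated correlation). Markers of GABAergic interneurons gave 0 of 22 and 0 adjusted over the list alone (camera adjusted p = 0.670, and adjusted p = 0.869 with an estimated correlation). Nuclear genes of oxidative phosphorylation gave 0 of 30 and 0 adjusted over the list alone (camera adjusted p = 0.451, and adjusted p = 0.869 with an estimated correlation). Ribosomal protein genes rose in 6 of 38 cases, 6 adjusted over the list alone (camera adjusted p = 4.7e-05, and adjusted p = 0.280 with an estimated correlation). Blood genes gave 1 up of 8, 1 adjusted over the list alone (camera adjusted p = 0.810, and adjusted p = 0.919 with an estimated correlation), with a median of -0.13 and a mean of 0.38.

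Markers of neighbouring tissue, of sex and of RNA content were measured in the hippocampal libraries too. Thalamus markers gave 1 up of 12, 1 adjusted over the list alone (camera adjusted p = 0.0824, and adjusted p = 0.510 with an estimated correlation). Central amygdala and striatum markers gave 1 up and 2 down of 17, 3 and 2 adjusted over the list alone (camera adjusted p = 0.397, and adjusted p = 0.720 with an estimated correlation). The transcription factor Etv1, a marker of basolateral neurons, fell by 0.37 ± 0.08, with 3 of 16 such genes down, 5 adjusted over the list alone (camera adjusted p = 0.00446, and adjusted p = 0.258 with an estimated correlation). Of the genes that check sex and identity only Xist, the RNA that silences an X chromosome, passed the count filter. It fell by 0.53 ± 0.10 in the hippocampus (adjusted p = 0.00438, edgeR), 1 of 1 adjusted over the list alone, and gave -0.06 ± 0.08 in the BLA; it was named after its values were seen. Rn7sk, a small nuclear RNA, and the gene Cdr1 passed the threshold at -2.92 ± 0.92 and -1.09 ± 0.34. Leaving out the libraries rich in 18S rRNA, all of them controls, ends both calls.

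In the BLA of APP/Tau mice glial genes rose too, with fewer genes called. Gfap rose from 50.1 ± 20.7 CPM in 10 controls to 485 ± 614 CPM in 9 APP/Tau mice, a change of 3.12 ± 0.54. Cst7 rose by 4.35 ± 0.80, Clec7a by 4.88 ± 0.94, Itgax by 3.52 ± 0.72, C4b by 2.07 ± 0.40, Trem2 by 1.20 ± 0.25 and Apoe by 0.57 ± 0.13. Cd74, the invariant chain of antigen presentation, rose by 2.61 ± 0.59 and the lymphocyte receptor Ly9 by 2.92 ± 0.60. Stard4, a cholesterol carrier, fell by 0.67 ± 0.14. With naive and trained mice together 273 of 23168 genes passed adjusted p < 0.05 (edgeR quasi-likelihood F test), 231 up and 42 down. The count depends on the method: DESeq2 calls 1188, limma-voom 64, the fit with a replicate block 44 and the fit with a striatal marker covariate 38. Leaving out each library in turn gives 45 to 2176. limma-voom, the replicate block and the covariate each end the calls of Trem2, Apoe, C4b, Clec7a, Itgax, Ly9 and Cd74. limma-voom also ends those of Gfap and Cst7. Of these genes only Gfap and Cst7 are called in every fit without 1 library. The replicate block is the title number, which names different mice and shows no pairing between groups (mean r -0.02). A call that it ends can therefore be lost power alone.

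Part of the microglial, lysosomal and myelin genes were called higher in the BLA. The adaptor Tyrobp rose by 1.45 ± 0.25 and the tetraspanin Cd9 by 1.13 ± 0.19. Of 30 disease-associated microglia genes 15 rose, 24 adjusted over the list alone, with a median of 1.13 (camera adjusted p = 8.1e-14, and adjusted p = 0.258 with an estimated correlation). C1qa rose by 1.16 ± 0.24 and C1qc by 0.90 ± 0.18. Complement and antigen presentation genes rose in 9 of 21 cases, 17 adjusted over the list alone (camera adjusted p = 1.5e-10, and adjusted p = 0.258 with an estimated correlation). The growth factor receptor Csf1r rose by 0.51 ± 0.09, with 3 of 18 homeostatic microglia genes up, 9 adjusted over the list alone (camera adjusted p = 4.9e-07, and adjusted p = 0.258 with an estimated correlation). The protease Ctss rose by 0.94 ± 0.20, with 5 of 26 lysosome genes up, 7 adjusted over the list alone (camera adjusted p = 0.00565, and adjusted p = 0.364 with an estimated correlation). Cnp, a myelin enzyme, rose by 0.61 ± 0.14 and Opalin, a myelin membrane protein, by 0.81 ± 0.19. Myelin genes rose in 3 of 20 cases and in all 20 adjusted over the list alone (camera adjusted p = 1.4e-13, and adjusted p = 0.258 with an estimated correlation). Tyrobp, Cd9 and Csf1r are called in every fit without 1 library, while C1qa, C1qc, Ctss, Cnp and Opalin are not and also lose their calls in limma-voom.

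Few astrocyte and interferon genes were called in the BLA. Aldoc, a glycolytic enzyme of astrocytes, rose by 0.34 ± 0.07, a call that ends in some fits without 1 library. Gfap is the only 1 of 23 reactive astrocyte genes called over all genes, while 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00120, and adjusted p = 0.337 with an estimated correlation). Interferon genes gave 0 of 21, and 2 up adjusted over the list alone (camera adjusted p = 0.000139, and adjusted p = 0.371 with an estimated correlation). Meningeal and vascular list scores (mean log2 CPM ± SD) lay higher in BLA APP/Tau mice than in controls too. Meningeal fibroblast scores were 2.24 ± 0.08 against 1.85 ± 0.14 in naive and 2.56 ± 0.44 against 2.03 ± 0.38 in trained mice. Endothelial and pericyte scores were 3.79 ± 0.15 against 3.55 ± 0.13 in naive and 3.98 ± 0.30 against 3.61 ± 0.18 in trained mice.

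**Figure D2:**
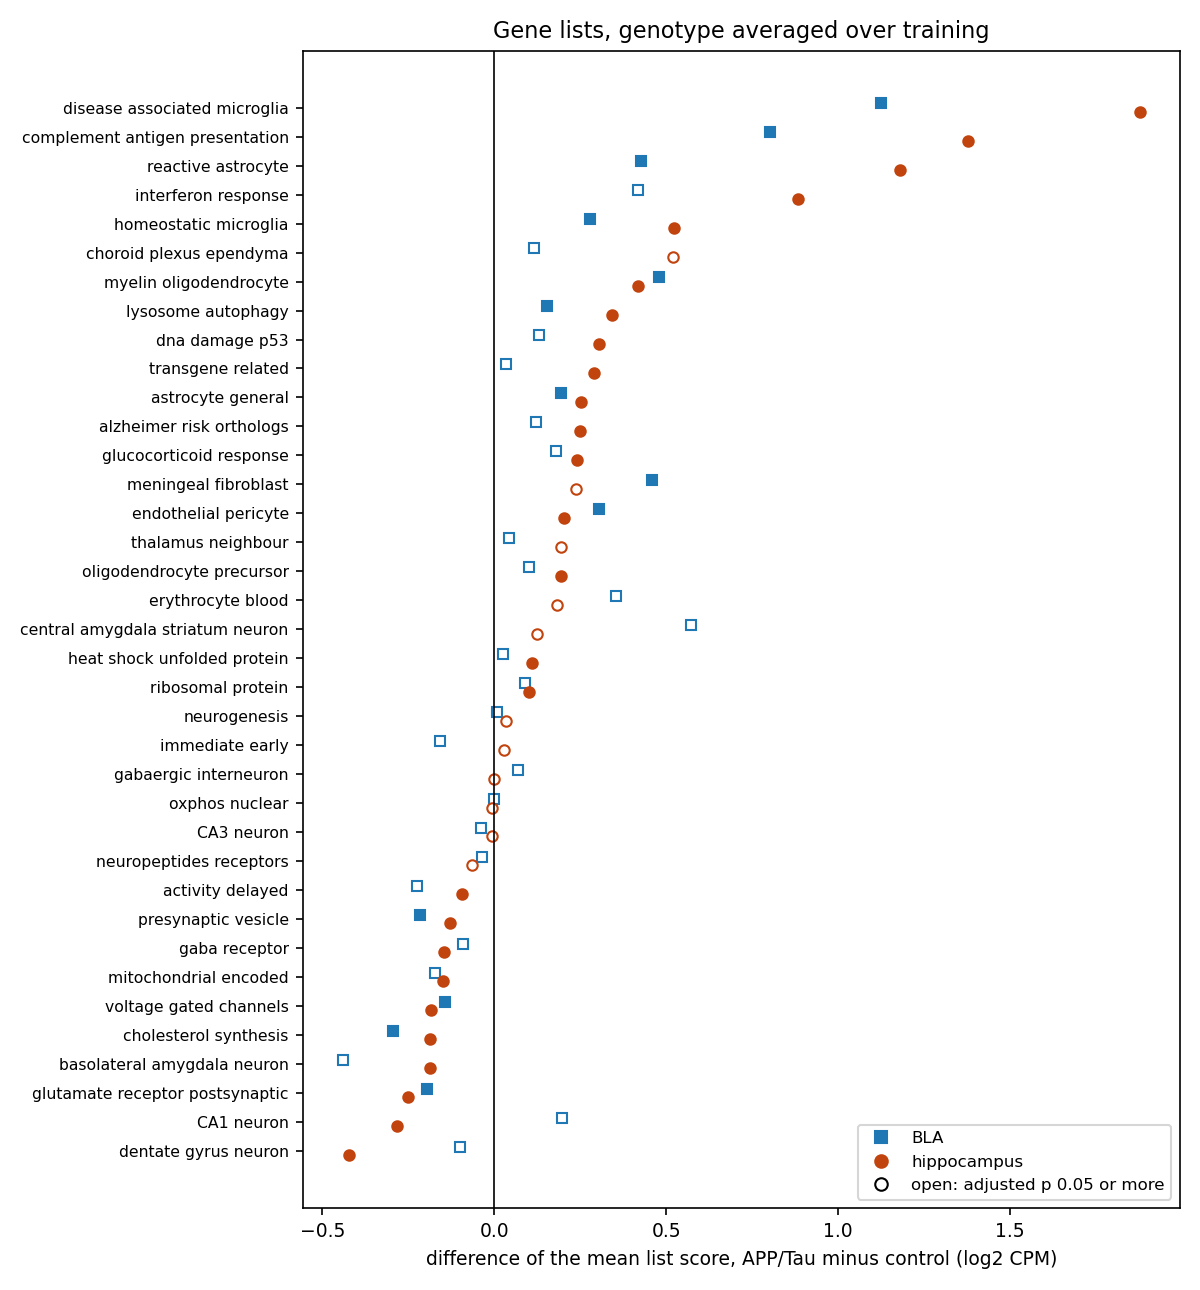
Difference of the mean list score, APP/Tau minus control (log2 CPM), for each gene list except sex and identity, over naive and trained mice. Squares are the BLA and circles the hippocampus, filled where the exact permutation adjusted p is below 0.05. With the sex and identity list counted, 13 lists in the BLA and 27 in the hippocampus have such a p. The disease-associated microglia and complement lists lie farthest to the right in both tissues.

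Glutamate receptor, presynaptic and cholesterol lists of the BLA sit below 0 with few single genes called. Grik1, a kainate receptor subunit, gave -0.89 ± 0.18 and is the only called gene of 34 glutamate receptor and postsynaptic genes. It is also a member of the chromosome 16 block described below, so no gene of this list outside that block is called. Adjusted over the list alone 7 fell (camera adjusted p = 7.1e-10, and adjusted p = 0.258 with an estimated correlation). Cholesterol synthesis genes fell in 1 of 22 cases, Stard4, and in 14 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 1.5e-10, and adjusted p = 0.258 with an estimated correlation). The calls of Grik1 and Stard4 end with the replicate block, with the striatal marker covariate and in some fits without 1 library. Presynaptic genes gave 0 of 30 and 0 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 1.0e-08, and adjusted p = 0.258 with an estimated correlation). Atf3 rose by 1.90 ± 0.35, a call that ends in limma-voom and in some fits without 1 library. Its heat shock list has a median of -0.09, a mean of 0.03 and a camera direction of down, so it gives no direction. Of 25 genes 1 rose over all genes, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0287, and adjusted p = 0.517 with an estimated correlation).

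Markers of neighbouring nuclei were compared between the BLA groups. All 18 central amygdala and striatum markers lie above 0 in APP/Tau mice, with a median of 0.47. None is called over all genes or adjusted over the list alone (camera adjusted p = 0.00121, and adjusted p = 0.545 with an estimated correlation). Basolateral neuron markers have a median of -0.56, with 0 of 16 called over all genes, and 2 up and 6 down adjusted over the list alone (camera adjusted p = 2.6e-05, and adjusted p = 0.285 with an estimated correlation). With the striatal marker score as a covariate the median of the glutamate receptor and postsynaptic genes goes from -0.15 to -0.13 and that of the cholesterol synthesis genes from -0.29 to -0.20. The median of the disease-associated microglia genes goes from 1.13 to 0.89, and 3 of them are called instead of 15.

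When naive and trained mice are taken apart, the hippocampus keeps more calls among trained mice. Naive APP/Tau against naive control mice gave 52 genes of 25791 in edgeR (28 up, 24 down, 5 and 5 mice). Prnp rose by 1.17 ± 0.08, App by 0.47 ± 0.06, Gfap by 2.22 ± 0.44 and the chemokine Cxcl5 by 4.74 ± 0.96. Nr4a2 fell by 0.61 ± 0.12, the autophagy kinase Ulk1 by 0.30 ± 0.06 and the sorting receptor Sorl1 by 0.26 ± 0.05. Leaving out the 2 libraries rich in 18S rRNA ends the calls of Gfap, Cxcl5, Nr4a2, Ulk1 and Sorl1 while their changes stay at 2.29, 4.84, -0.64, -0.31 and -0.24. It leaves 21 genes, and leaving out any single naive control leaves 18 to 23. Mapt at 0.22 ± 0.05 (edgeR adjusted p = 0.0507), C4b at 2.28 ± 0.48 (adjusted p = 0.0507) and Trem2 at 1.67 ± 0.39 (adjusted p = 0.0725) did not pass. The disease-associated microglia list has 6 of 30 genes up in naive mice, 25 adjusted over the list alone (camera adjusted p = 8.0e-12, and adjusted p = 0.422 with an estimated correlation).

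Trained APP/Tau against trained control mice gave 721 genes in the hippocampus with edgeR (684 up, 37 down, 4 and 6 mice). Gfap rose by 2.75 ± 0.43, C4b by 2.93 ± 0.48, Trem2 by 2.03 ± 0.38, Cd74 by 3.97 ± 0.70 and the complement component C3 by 5.35 ± 1.01. The disease-associated microglia list has 25 of 30 genes up, 29 adjusted over the list alone (camera adjusted p = 1.1e-19, and adjusted p = 0.231 with an estimated correlation). The interaction calls 0 genes, so the larger count in trained mice is not shown to be a difference between the conditions. Leaving out APP/Tau trained replicate 1 takes the trained count to 62, and leaving out replicate 2 takes it to 2234. Gfap, C4b and Cd74 are called in every fit without 1 library, Trem2 and C3 are not.

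In the BLA the separate comparisons call few genes. Naive mice gave 9 genes of 23168 (3 up, 6 down, 5 and 5 mice) and trained mice 10 (4 up, 6 down, 4 and 5 mice), with edgeR. The same 6 chromosome 16 genes fell in both, and Prn, Lamr1-ps1 and 4930590L14Rik rose in both; the calls of Prn end in some fits without 1 library. The microglial nucleotide receptor P2ry6 rose in trained mice by 0.91 ± 0.16 (edgeR adjusted p = 0.0484), a call that ends under several other settings. Gfap gave 2.27 ± 0.73 in naive mice (edgeR adjusted p = 0.272) and 3.98 ± 0.80 in trained mice (adjusted p = 0.111). C4b gave 1.46 ± 0.54 and 2.68 ± 0.58 (edgeR adjusted p = 0.296 and 0.129), so neither gene passed. Immediate early genes of naive mice have a median of -0.50, with 0 of 29 called over all genes and 12 down adjusted over the list alone (camera adjusted p = 1.4e-07, and adjusted p = 0.388 with an estimated correlation). With the striatal marker score as a covariate that median is -0.31.

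A block of neighbouring genes on chromosome 16 fell by about 1 log2 unit in both tissues of APP/Tau mice. These genes were grouped after their values were seen. Cct8, a chaperonin subunit, stood at 98.5 ± 6.98 CPM in 9 APP/Tau mice and 205 ± 22.5 CPM in 10 controls in the BLA, a change of -1.05 ± 0.06. The ubiquitin ligase Ltn1 fell by 1.15 ± 0.06, Rwdd2b, a protein of unassigned function, by 1.13 ± 0.08, the methyltransferase N6amt1 by 1.04 ± 0.09, the deubiquitinase Usp16 by 0.97 ± 0.05, the heme-responsive repressor Bach1 by 0.85 ± 0.08 and Grik1 by 0.89 ± 0.18. In the hippocampus Cct8 fell by 0.99 ± 0.04 and Ltn1 by 1.12 ± 0.04. In the BLA 11 of 12 tested segment genes lie below 0 and 8 are called, and the 7 with at least 1 CPM have a median of -1.04. In the hippocampus all 13 lie below 0, 10 are called, and the 8 with at least 1 CPM have a median of -1.0. The 20 flanking genes have medians of 0.09 and 0.01. Tiam1, the first tested gene after the segment in the hippocampus, fell there by 0.49 ± 0.10 (edgeR adjusted p = 0.00397) and was not called in the BLA (adjusted p = 0.987); it was named after its values were seen.

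**Figure D3:**
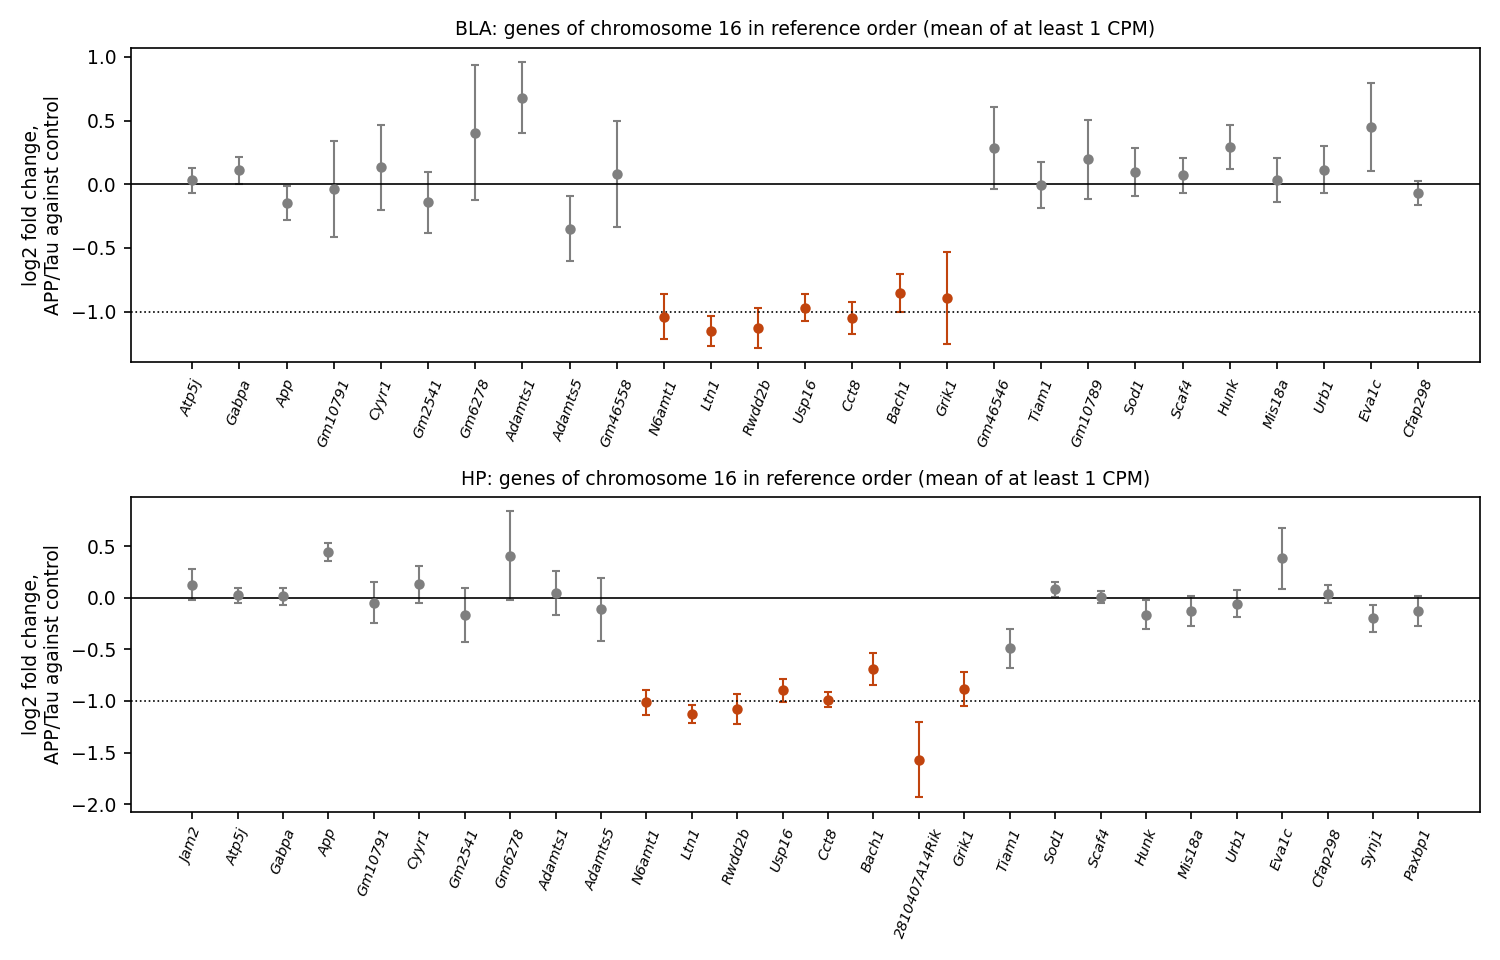
Log2 fold change of chromosome 16 genes in reference order, APP/Tau against control, with 95% intervals; red points are the segment genes, grey points the 20 flanking genes of each tissue, and the dotted line marks -1. The segment medians are -1.04 in the BLA and -1.0 in the hippocampus, and the flank medians are 0.09 and 0.01.

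Lamr1-ps1, a pseudogene of the ribosomal protein gene Rpsa, has reads only in APP/Tau mice. It holds 0 counts in all 21 control libraries, 443 in the 9 APP/Tau libraries of the BLA and 2337 in the 9 of the hippocampus. With a floor of 3 counts over the control libraries the change is at least 170-fold in the BLA and at least 902-fold in the hippocampus; these bounds cover counting error only, and 3 counts are fewer than 3 fragments if the mates of a pair were counted separately. Rpsa, its paralog, gave 0.15 ± 0.08 in the BLA (adjusted p = 0.314, edgeR) and 0.04 ± 0.04 in the hippocampus (adjusted p = 0.567). In the BLA the pseudogene was named after its values were seen.

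The genotype effect differed between the tissues for 7 of 26725 genes (2 larger and 5 smaller in the BLA; edgeR quasi-likelihood F test). The difference, BLA minus hippocampus, is -0.60 ± 0.08 for App and -0.54 ± 0.10 for Prnp, and -0.65 ± 0.12 for the overlapping Prn. Ptprc, the leukocyte phosphatase CD45, differs by -3.0 ± 0.43. In the BLA it stood at 11.7 ± 5.32 CPM in 9 APP/Tau mice and 24.7 ± 9.16 in 10 controls. In the hippocampus it stood at 10.6 ± 6.93 in 9 and 2.79 ± 0.567 in 11. Il1r1, the interleukin 1 receptor, differs by 0.96 ± 0.18, and Relb, an NF-kB subunit, by -0.63 ± 0.12. Only the calls of App and Ptprc hold when any single library, or the libraries rich in 18S rRNA, are left out. Of 5 transgene-related genes 2 are lower (3 adjusted over the list alone; camera adjusted p = 4.1e-06, and adjusted p = 0.0226 with an estimated correlation). Reactive astrocyte genes gave 0 of 26 and 10 down adjusted over the list alone, with a median of -0.91 (camera adjusted p = 5.1e-07, and adjusted p = 0.667 with an estimated correlation). CA1 markers gave 0 of 10 and 6 up adjusted over the list alone (camera adjusted p = 3.1e-05, and adjusted p = 0.153 with an estimated correlation). Of the 231 genes up in the BLA and measured in both tissues, 202 are also up in the hippocampus, and of 41 down, 20 are shared. The shared falling genes include the 8 chromosome 16 block genes called in the BLA. Prnp, Prn, Lamr1-ps1 and the neighbouring Ugt1a genes are among the shared rising ones. A mouse can have given both tissues, so the calls of the tissues need not be independent.

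Fear conditioning changed no single gene at the threshold in either tissue of control mice. In the BLA of controls Fos, an immediate early gene of neuronal activity, stood at 19.2 ± 9.81 CPM in 5 naive and 25.7 ± 9.30 CPM in 5 trained mice (0.41 ± 0.35). Egr1 gave 0.26 ± 0.21, the synaptic gene Arc -0.03 ± 0.25, Npas4 0.05 ± 0.17 and the growth factor Bdnf -0.14 ± 0.44. The smallest p-values, none past the threshold, belong to Tmsb15l and Tmsb15b2, actin-binding thymosins (0.85 ± 0.17 and 0.80 ± 0.18), the pseudogene entries Gm10284 and Gm12576, and the sialyltransferase St6galnac2 (0.76 ± 0.17). edgeR calls 0 of 23168 genes, with 484 at unadjusted p < 0.05 against 1158 by chance; DESeq2 calls 1 and limma-voom was run for the averaged and interaction fits. In the hippocampus of controls Fos stood at 13.6 ± 6.39 CPM in 5 naive and 19.2 ± 5.55 CPM in 6 trained mice (0.49 ± 0.31), Egr1 gave 0.46 ± 0.25, Npas4 0.34 ± 0.18, Bdnf 0.26 ± 0.18 and Arc 0.08 ± 0.23. There edgeR calls 0 of 25791 genes (624 at unadjusted p < 0.05 against 1290 by chance) and DESeq2 0; the smallest p-values belong to Gm6947, Ankrd55, an ankyrin repeat protein, Gm16118, Tmsb15l and E330020D12Rik, none past the threshold.

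In APP/Tau mice most immediate early genes of the BLA lie higher after conditioning, but none passes the threshold. Fos stood at 9.96 ± 4.77 CPM in 5 naive and 27.4 ± 7.88 CPM in 4 trained mice (1.46 ± 0.38, edgeR adjusted p = 0.708). Egr1 gave 0.89 ± 0.22 (edgeR adjusted p = 0.596) and Arc 0.65 ± 0.26 (adjusted p = 0.841), while Npas4 gave -0.21 ± 0.18 and Bdnf 0.20 ± 0.47. The smallest p-values, none past the threshold (each edgeR adjusted p = 0.476), belong to the collagen hydroxylase P4ha1 (0.48 ± 0.09), the cap methyltransferase Cmtr2 (-0.57 ± 0.11), the cell cycle regulator Rgcc (0.58 ± 0.12), the heat shock protein Hspb1 (1.16 ± 0.24) and Nr4a2 (1.5 ± 0.31). Immediate early genes lie above 0 in 28 of 29 cases with a median of 0.52; 0 pass over all genes and 15 rose adjusted over the list alone (camera adjusted p = 2.9e-19, and adjusted p = 0.107 with an estimated correlation; exact permutation adjusted p = 0.377, where 126 permutations are too few for a single list to pass). Heat shock genes gave 0 of 25 and 4 up adjusted over the list alone (camera adjusted p = 1.3e-10, and adjusted p = 0.107 with an estimated correlation). Glial genes lie above 0 in this comparison too. Disease-associated microglia genes do so in 30 of 30 cases with a median of 0.56, with 0 over all genes and 0 adjusted over the list alone (camera adjusted p = 8.9e-07, and adjusted p = 0.509 with an estimated correlation). Reactive astrocyte genes do so in 20 of 23 cases with a median of 0.55, with 0 over all genes and 1 up adjusted over the list alone (camera adjusted p = 2.6e-06, and adjusted p = 0.348 with an estimated correlation). edgeR calls 0 of 23168 genes, with 1356 at unadjusted p < 0.05 against 1158 by chance, and DESeq2 calls 14.

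**Figure D4:**
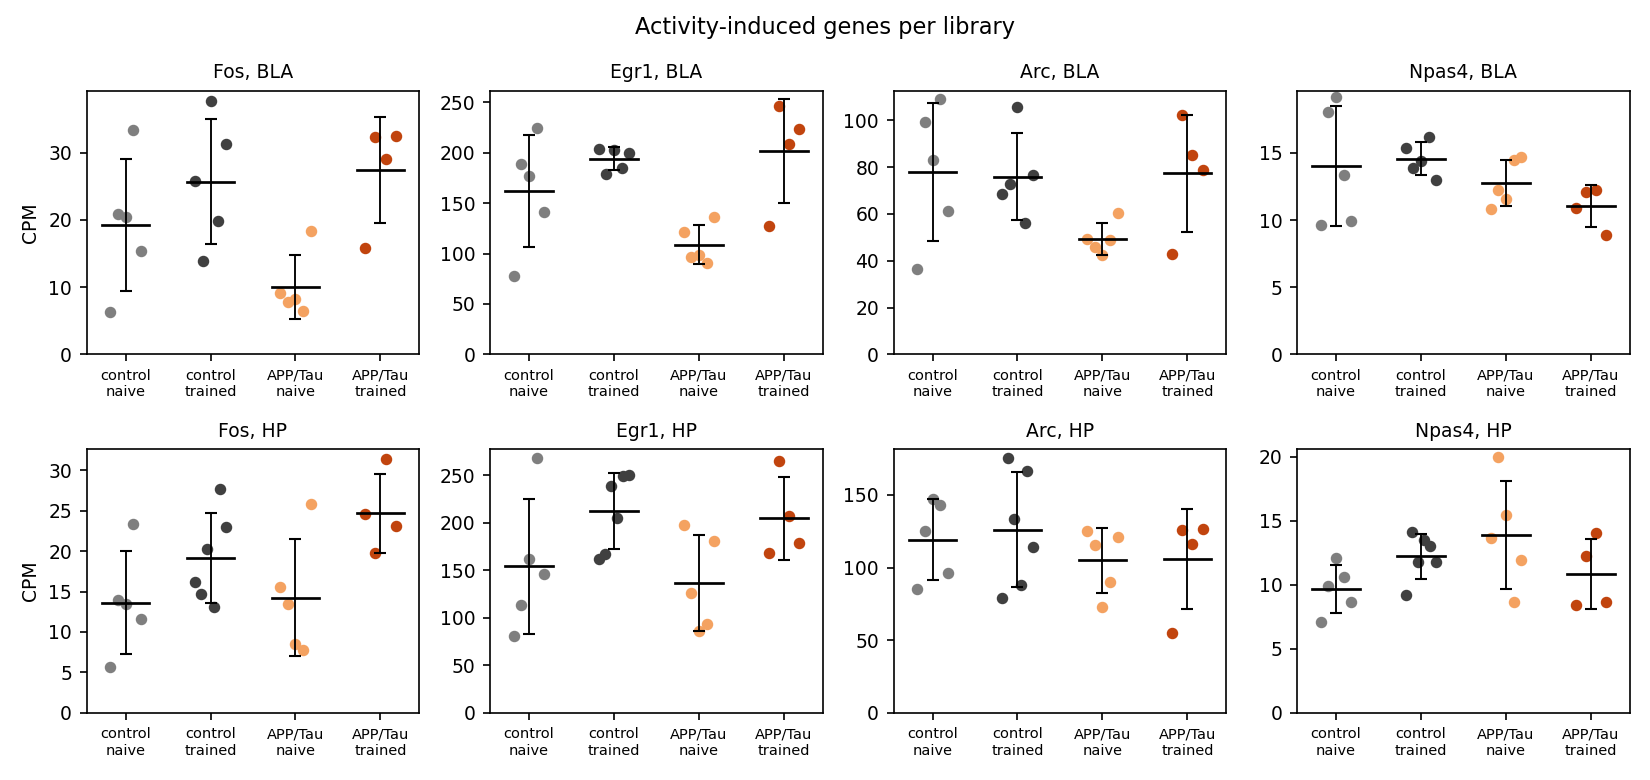
Levels of Fos, Egr1, Arc and Npas4 in each library (CPM) for naive and trained control and APP/Tau mice in the BLA and the hippocampus; points are libraries and bars mean ± SD. In the BLA Fos averages 9.96 CPM in naive and 27.4 CPM in trained APP/Tau mice, against 19.2 and 25.7 CPM in controls.

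In the hippocampus of APP/Tau mice Fos stood at 14.2 ± 7.23 CPM in 5 naive and 24.7 ± 4.87 CPM in 4 trained mice (0.79 ± 0.34), Egr1 gave 0.58 ± 0.28, Arc 0.01 ± 0.25, Npas4 -0.36 ± 0.20 and Bdnf 0.10 ± 0.20, none past the threshold. The smallest p-values, also not past it, belong to Ttc27, a repeat protein (-0.31 ± 0.05, edgeR adjusted p = 0.355), Gm31036, P4ha1 (0.39 ± 0.09), the laminin Lamc1 (0.25 ± 0.06) and the phospholipase Plch1 (-0.39 ± 0.10). Immediate early genes lie above 0 in 25 of 29 cases; 0 pass over all genes and 3 rose adjusted over the list alone (camera adjusted p = 7.0e-08, and adjusted p = 0.583 with an estimated correlation). edgeR calls 0 of 25791 genes (1184 at unadjusted p < 0.05 against 1290 by chance) and DESeq2 calls 2.

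The response to conditioning did not differ between genotypes for any gene in edgeR. In the BLA the smallest interaction p-values belong to Baat, a bile acid enzyme (-3.76 ± 0.88), Rgcc (0.69 ± 0.16), the Fc receptor-like Fcrlb (-1.3 ± 0.31), the cytokine subunit Il23a (-4.93 ± 1.18) and D330025C20Rik (-1.28 ± 0.32), each with edgeR adjusted p = 0.949 and not past the threshold. Immediate early genes lie above 0 in 28 of 29 cases with a median of 0.48, with 0 over all genes and 0 adjusted over the list alone (camera adjusted p = 1.9e-09, and adjusted p = 0.656 with an estimated correlation). In the BLA 894 genes had unadjusted p < 0.05 against 1158 by chance, and DESeq2 and limma-voom call 0. In the hippocampus 0 of 25791 genes pass (1005 at unadjusted p < 0.05 against 1290 by chance; DESeq2 3, limma-voom 0), and the smallest p-values, none past the threshold, belong to Gm6947, Gm33182, Gm19810, the protease Adamts6 (-0.60 ± 0.14) and Gm31036. On simulated changes of 2-fold the interaction test recovered 58.2% of changed genes in the BLA and 79.1% in the hippocampus, so changes of that size in single genes can be missed.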

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

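The splits of the BLA libraries and the tests of the chromosome 16 block, of Lamr1-ps1 and of the immediate early genes were chosen only after these results were seen.

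The genes that the rule names in advance, a few list scores and a few quality values were searched within each group for a library far from the rest. Of 184 groups, 19 hold such a library. A search of this kind marks about 1 in 20 groups by chance if values are normal and independent. CPM values need not be normal, and several marks come from the same mouse, so the number of marks cannot be set against that rate. APP/Tau naive mouse 5 stands highest in the hippocampus for Gfap (4882 CPM, others 901 to 1595), Cst7 (20.5 CPM, others 0.396 to 5.79), Trem2 (64.0 CPM, others 13.7 to 21.3), Apoe (4888 CPM, others 1824 to 1962) and C4b (479 CPM, others 75.6 to 152). BLA library 5 of the APP/Tau naive group is highest for Cst7 (4.89 CPM, others 0.190 to 0.852), Fos (18.3 CPM, others 6.45 to 9.05) and the immediate early score (4.35, others 3.94 to 3.99). BLA control trained 2 is highest for C4b (24.8 CPM, others 6.50 to 9.89) and for the score of disease-associated microglia (2.69, others 2.18 to 2.33). Hippocampal control trained 6 has the most Mapt (603.8 CPM, others 529.6 to 548.3), and hippocampal control naive 4 the most Bdnf (64.8 CPM, others 35.3 to 42.8). Hippocampal APP/Tau trained 1 has the least Arc (54.6 CPM, others 116 to 126).

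Some of these libraries differ in composition. 18S rRNA takes 5.18% of the counts in hippocampal control naive 1 (others 0.0497 to 0.170%), 1.99% in hippocampal control trained 1 (others 0.0504 to 0.286%) and 0.893% in BLA control naive 1 (others 0.201 to 0.339%). BLA control naive 1 also has the fewest genes with a count (26442, others 28180 to 28692). Hippocampal control trained 1 is lowest for Prnp (707 CPM, others 871 to 913) and highest for Cst7 (0.652 CPM, others 0.0797 to 0.284).

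The averaged genotype effect differs between the tissues for 7 genes under edgeR, given as BLA minus hippocampus in log2. These are App (−0.60, adjusted p 0.000228), Ptprc (−3.0, adjusted p 0.000394), Prn (−0.65, adjusted p 0.0226), Prnp (−0.54, adjusted p 0.0226) and Relb (−0.63, adjusted p 0.0486), and in the other direction Il1r1 (0.96, adjusted p 0.0226) and Gm41107 (10.3, adjusted p 0.0486).

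For each comparison 100 groupings of the same libraries were fitted, the real one among them. In the BLA 1 of 100 called as many genes as the real grouping for the averaged genotype effect (273 genes, highest other 0) and 1 of 100 for naive mice (9 genes, highest other 0). For trained BLA mice 4 of 100 did (10 genes, highest other 1151). The 9 naive genes are 6 of the chromosome 16 block with Prn, Lamr1-ps1 and 4930590L14Rik. Their splits therefore say little on a wider response in naive BLA mice. The training effects and the interaction call 0 genes, which all 100 groupings match, with highest others of 5 in BLA controls, 328 in BLA APP/Tau mice and 4 for the BLA interaction. In the hippocampus 1 of 100 called as many for the averaged effect (2854 genes, highest other 1336), 1 of 100 for naive mice (52 genes, highest other 1) and 1 of 100 for trained mice (721 genes, highest other 449). All 100 match the 0 genes of the hippocampal training effects and interaction, with highest others of 5 in controls, 4788 in APP/Tau mice and 970 for the interaction. For the tissue difference 1 of 100 called as many (7 genes, highest other 2).

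Several splits call far more genes than the real grouping, so the libraries hold structure that genotype and training labels do not fully name. In the BLA the split with 1151 genes sets APP/Tau trained 2 and control trained 3, 4 and 5 against the rest. The rest are APP/Tau trained 1, 3 and 4 with control trained 1 and 2, so the genotypes stay largely apart. The real grouping of trained BLA mice calls 677 genes without APP/Tau trained 2. In BLA APP/Tau mice the split with 328 genes sets trained 1, 3 and 4 with naive 2 and 5 against trained 2 with naive 1, 3 and 4. In hippocampal APP/Tau mice the split with 4788 genes sets naive 1 and 5 with trained 1 and 3 against naive 2, 3 and 4 with trained 2 and 4. What divides these mice was not tested.

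A block of neighbouring genes on chromosome 16 is lower in every APP/Tau library, with a median log2 fold change of −1.0 in the tissue nearer to 0, the value that loss of 1 of 2 copies gives. Of 10000 shuffled gene orders 0 held a run as long as the 7 called genes of the BLA (longest 3) or the 8 of the hippocampus, Tiam1 included (longest 6), so chance clustering of calls is argued against. By the mean over the block the lowest control and the highest APP/Tau library are still 0.70 log2 CPM apart, so a few aberrant libraries do not make the pattern. A deletion at a transgene insertion site and a lower-expressed haplotype carried along with a transgene could both give a median of −1.0, and the counts do not separate them.

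Reads at Lamr1-ps1 occur in APP/Tau libraries only: 0 libraries are out of place over both tissues. Control libraries hold 0 counts there although their Rpsa counts sum to 68212 in the BLA and 151747 in the hippocampus, so reads shared with Rpsa do not explain it. Reads that start in a transgene or at its insertion site could give this pattern. Which transgene, and whether the locus is an insertion site, stays open without the reads.

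Immediate early genes of the BLA lie higher in trained than in naive APP/Tau mice, with a median log2 fold change of 0.52. With the striatal marker score as a covariate the median is 0.47. This argues against striatal tissue, as far as this score measures it, as the main source. It does not cover other neighbouring tissue. The CA1 marker score of the BLA was 4.85 ± 0.48 in trained and 4.43 ± 0.09 in naive APP/Tau mice, and its part in the difference was not tested. Exact permutation of the list score, 2-sided, gives p 0.0238 for this difference (adjusted p 0.377 over the lists, where 126 permutations are too few for a single list to pass). The same permutation gives p 0.0988 for the interaction. It shuffles training labels within each genotype, so this p is set against no training effect in either genotype and not against equal effects. In the same mice the lists of disease-associated microglia and reactive astrocytes move as far, with medians of 0.56 and 0.55. Spread between mice and a response that differs by genotype could each give these values, and they are not separated here.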

How the results depend on the processing

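Leaving out the 18S-rich libraries, the striatal marker covariate and the exact permutation of list scores were chosen only after the results were seen. With DESeq2 the averaged genotype effect calls 1188 genes in the BLA (273 with edgeR) and 4311 in the hippocampus (2854). Naive mice give 108 in the BLA (9) and 711 in the hippocampus (52), trained mice 200 (10) and 1569 (721). The training effect, 0 with edgeR, gives 1 in BLA controls, 14 in BLA APP/Tau mice and 2 in hippocampal APP/Tau mice, the hippocampal interaction 3, and the tissue difference 41 (7). With a block on the title number the averaged BLA effect calls 44 and hippocampal trained mice 1456. With a block on the library number the tissue difference calls 30. The averaged BLA effect calls 64 with limma-voom and 38 with the striatal marker covariate. Fits of only the 2 groups compared call 27 in naive BLA mice, 6 in trained BLA mice and 21 in naive hippocampal mice, and the filter at a mean of 1 CPM calls 83 in the last. Without the 18S-rich libraries the hippocampus calls 1803 averaged, 21 naive and 227 trained, and the tissue difference 2. The cause was not tested. The heat shock list in the BLA, averaged, turns its direction under exact permutation of the list score (2-sided adjusted p 0.664).

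With 1 library left out the averaged BLA effect runs from 45 (without APP/Tau trained 1) to 2176 (without APP/Tau trained 2). It is 69 without APP/Tau trained 3, and 118, 159 and 88 without APP/Tau naive 2, 3 and 5. It is 91, 171, 119 and 117 without control naive 2, 3, 4 and 5, and 75, 1260, 100, 73 and 116 without control trained 1, 2, 3, 4 and 5. Naive BLA mice run from 8 (without control naive 2) to 16 (without APP/Tau trained 2). Trained BLA mice run from 8 (without APP/Tau trained 1) to 677 (without APP/Tau trained 2), with 18 without APP/Tau trained 4. The averaged hippocampal effect runs from 1171 (without APP/Tau trained 1) to 4465 (without APP/Tau trained 2), with 1190 without APP/Tau trained 3 and 1787 without APP/Tau naive 5. Naive hippocampal mice run from 18 (without control naive 2) to 260 (without APP/Tau trained 2). There the count is 163 and 33 without APP/Tau trained 1 and 3, and 24, 104 and 21 without APP/Tau naive 2, 4 and 5. It is 22, 23, 20 and 21 without control naive 1, 3, 4 and 5, and 27, 33, 25 and 34 without control trained 2, 3, 4 and 5. Trained hippocampal mice run from 62 (without APP/Tau trained 1) to 2234 (without APP/Tau trained 2). There it is 98 and 1480 without APP/Tau trained 3 and 4, 1741 without APP/Tau naive 5, and 377, 387, 418, 361, 427 and 370 without control trained 1, 2, 3, 4, 5 and 6. The tissue difference runs from 2 (without BLA APP/Tau trained 1, or hippocampal control naive 2) to 25 (without hippocampal APP/Tau trained 2). It is 17, 4, 3 and 16 without BLA APP/Tau trained 2, control naive 1, control naive 5 and control trained 2, and 4 without hippocampal APP/Tau trained 1. Training effects and interactions stay at 0 throughout.

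Every fit without 1 library calls 41 of the 273 averaged BLA genes, 1045 of the 2854 averaged hippocampal genes, 8 of 9 and 8 of 10 in naive and trained BLA mice, 18 of 52 and 57 of 721 in naive and trained hippocampal mice, and 2 of 7 for the tissue difference (App and Ptprc). No named gene changes sign past the threshold. Of the lists called by camera for the averaged effect, 23 in the BLA and 26 in the hippocampus, the estimated correlation keeps 0 and 1, fry 12 and 25, and exact permutation 13 and 25. Title numbers show no pairing between groups (mean r −0.02 in the BLA and 0.03 in the hippocampus). BLA and hippocampal libraries with the same library number have a mean r of 0.183 against −0.045 for other pairs of their group, and 18 of 19 BLA libraries match best with their own number, a hint from the data that they share a mouse.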

Other observations

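The correlations of list scores between tissues and the look at the Ugt1a genes were chosen only after the results were seen.

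If the library number names the mouse, which is a hint and not given by the labels, the glial scores of an APP/Tau mouse go together in its BLA and hippocampus. Deviations of the list scores from the group mean were correlated between BLA and hippocampus, with 2-sided exact permutation within groups and adjustment over 12 relations. Over 9 APP/Tau mice r is 0.95 for disease-associated microglia (adjusted p 0.00833), 0.95 for reactive astrocytes (adjusted p 0.0125) and 0.91 for complement and antigen presentation (adjusted p 0.0125). For each list r was also taken without the 2 mice whose BLA deviation lies farthest from the median of these deviations. It is then 0.92, 0.92 and 0.86. Mice extreme in the hippocampus alone stay in. The interferon list has r 0.84 (adjusted p 0.0357) but 0.41 without its 2 farthest mice, and myelin has r −0.13. Over 10 controls r is 0.57 for disease-associated microglia, 0.44 for complement and antigen presentation, 0.57 for interferon and −0.57 for reactive astrocytes. None of these control values passes adjusted p 0.05. Immediate early genes go together in controls (n 10, r 0.79, adjusted p 0.0357) as well as in APP/Tau mice (r 0.70, adjusted p 0.0493), with 0.59 and 0.48 without the 2 farthest mice. Rank correlations give adjusted p 0.0525 and 0.180 for these genes and 0.0975 for the interferon list in APP/Tau mice, so these 3 relations do not hold by rank.

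The Ugt1a genes on chromosome 1 form a run of 8 called genes that rise with genotype in both tissues when naive and trained mice are averaged. In edgeR Ugt1a6a rises by 0.94 ± 0.19 in the BLA (adjusted p 0.0227) and by 1.53 ± 0.24 in the hippocampus (adjusted p 0.000646); the BLA call ends in limma-voom, with the replicate block, with the striatal marker covariate and in some fits without 1 library. The 8 genes share their last exons, so they count as a single event.

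The amount of glial response differs widely between APP/Tau mice. A test would measure plaque load and phosphorylated tau in the same mice: if pathology drives the spread, the score of disease-associated microglia follows plaque load in both tissues.

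Prnp and Prn rise together, in edgeR by 1.11 and 1.41 in the hippocampus (adjusted p 2.9e-11 and 1.3e-11) and by 0.58 and 0.78 in the BLA (adjusted p 0.00234 and 0.00022). The J9 line carries a PDGF-B promoter and the PS19 line a mouse Prnp promoter, which is knowledge from outside these data. The hypothesis is that Prnp exon reads of the Tau transgene are counted as Prnp and Prn. A test on the reads would ask whether the added reads sit in the untranslated exons of Prnp alone and whether their mates lie in human MAPT.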
